A study of Homo sapiens with 12 samples.

How the data were processed

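Polysomal RNA of CHP134 neuroblastoma cells was measured on 12 single-colour (Cy3) Agilent arrays, 3 for each of 4 groups: vehicle, 15 µM isorhamnetin, 5 µM 13cRA and the combination, all after 24 h. Per the labels, ribosomes were held on the RNA with 100 µg/ml cycloheximide for 4 min before lysis, and every replicate was a separate experiment starting from cell seeding. RNA not bound to polysomes was not analysed here, so a change may be read in the polysomal RNA only.

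Per the file headers, the scanner files hold the processed signal as an intensity on a linear scale, background-subtracted and detrended within the array by Agilent Feature Extraction, and not normalized between arrays; they also hold the spot mean and local background as intensity. The software version in the labels' processing notes, 10.7.7.1, differs from that in the file headers, and probe coordinates are those of genome build hg18. The deposited value table holds log2 values for 26209 probes that the authors normalized between arrays by a method they do not state. It was set against the log2 spot mean and the log2 processed signal, both quantile-normalized. It was closer to the spot mean (median r = 0.9996, median absolute difference 0.046) than to the processed signal (0.9924 and 0.233). This compares signals and not normalization methods, so the method stays unknown.

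Of 45015 spots per array, 43376 were not controls. Between 51 and 83 spots per array marked as non-uniform or population outliers were left out, and spots of the same probe were averaged, which gave 41000 probes. The processed signal was log2-transformed and the 75th percentile of each array subtracted. Probes had to be well above background, by the flag of the extraction software, on all 3 arrays of at least 1 group; 25787 did, 21256 of them with a gene symbol. Probes were named by their sequence accession (25398 probes), a current symbol (2510), an older symbol (789) or the name in the file (1659), and 10644 had none. The probe with the highest mean signal stood for each gene, which gave 14330 genes, 9134 with a single kept probe. A gene was taken as above background on an array when any of its probes was.

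The 12 arrays were fitted together in a linear model with limma 3.58.1 (R 4.3.3, the package data.table in version 1.17.8), with empirical Bayes moderation, and 5 pairwise contrasts, the interaction and the F test over the 4 groups were taken from it. Benjamini-Hochberg adjusted p under 0.05 was the threshold in each contrast, two-sided. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Where no array of a group was above background for a gene, the bound was the mean of the brighter group minus the mean over the arrays of the dim group of the lowest signal well above background on the array, or of the gene's own signal if higher. Where arrays of a group were above background only on another probe of the gene, the bound is that of the brightest probe and is given as such. No such bound exists for an interaction.

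Each of 3 slides held 4 arrays, 1 of each group, and slide and replicate number coincided. After subtraction of the group mean, the 18 pairs of arrays with the same number had r between 0.39 and 0.71 (median 0.58) across genes, pairs with other numbers between −0.53 and 0, and 12 of 12 arrays were closest to one with their own number. The numbers therefore pair the arrays, and a fit with the number as a block is printed beside the total of each contrast and beside some of the other counts; the fit without the block had been chosen before the data were examined and was kept as the one reported. Within-slide values are the differences between the arrays of a slide.

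The choices named here, the gene lists and the rule for naming genes were set before the data were examined, except where the text says otherwise. The named genes were, for each comparison with vehicle, the 10 largest rises and 10 largest falls among genes past the threshold whose 3 treated arrays all lay on the same side of the 3 vehicle arrays, a separation that chance gives in 10% of genes at 3 against 3 for either direction together. For the other contrasts they were the 5 largest rises and 5 largest falls, skipping uncharacterised and Y-linked symbols. Added were the 3 members with the smallest adjusted p of up to 8 lists that passed their test or had at least 3 members past the threshold, and, whatever their values, genes fixed by name, among them CYP26A1, RARB, DHRS3, MYCN, RET, CYP1A1, CYP1B1, HMOX1, CDKN1A and CCND1. Some genes that meet this rule are not reported here. The 27 gene lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists within a contrast. The same test with the correlation estimated from the data and fry, which tests whether a list moves without comparing it with other genes, were run as alternatives. For lists with members below background, the median was also taken with each value raised to the lowest signal well above background on its array.

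The pipeline was tested on simulated data with 14314 genes and changes of known size put in. Of the genes changed 2-fold, 76% to 90% were recovered in the pairwise contrasts and 42% in the interaction, and of those changed 1.5-fold 40% to 56% and 14%. Between 3 and 8 unchanged genes were called per contrast. The list test called the 1 list of 27 that was shifted by 0.5 log2 and 0 others. Simulated genes varied independently of each other and without slide differences, so false list calls from correlated genes could not show there. The number of arrays limits the precision, most of all for the interaction.

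The alternatives tried were quantile normalization, scaling to the array median, normexp background correction with an offset of 50, no filter and a filter on all 12 arrays for dim probes, outlier spots kept, the mean of all probes of a gene, every probe on its own, trended and robust moderation, the replicate block, the deposited value table, a 2-fold minimum, only the 2 groups compared, and leaving out each array and each replicate number. Control spots were left out of all tests, and probes without a gene symbol were tested apart from the genes. For the comparison of arrays by chance, the 6 arrays of a pairwise contrast were split in all 10 ways and the 12 arrays relabelled 100 times (seed 1), freely and also within slides, each set of groups counted once.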

Results

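Polysomal RNA, the messenger RNA bound to several ribosomes at once, was measured in CHP134 cells, a human neuroblastoma cell line, after 24 h of treatment. The 4 groups were vehicle (DMSO), 15 µM isorhamnetin (a plant flavonoid), 5 µM 13cRA (isotretinoin, 13-cis-retinoic acid) and the combination of both, with 3 biological replicates each, every replicate started from a separate seeding of cells. Each of the 12 RNA samples was hybridised to its own single-colour array. Per array, 61.7% to 67.9% of the 43376 non-control spots were well above background, 0 spots were saturated, and the 75th percentile of the signal was between 1021 and 1384 intensity units. Replicates correlated across genes with r of at least 0.991, where genes are not independent replicates. The number of arrays, 3 per group, limits the precision of every value below.

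Values are log2 signals relative to the 75th percentile of the array. Differences are log2 changes with the standard error of the limma fit after ±, n = 3 arrays per group, for 14330 genes. A gene is said to have risen or fallen when its adjusted p was under 0.05. Where no array of a group was above background for a gene, the change is given as a lower bound ("at least"), computed against the lowest signal well above background on those arrays. Each of the 3 slides held 1 array of each group and 1 replicate number, so counts are also given with the slide as a block. Probe positions refer to genome build hg18.

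Isorhamnetin was compared with vehicle to see what the flavonoid did on its own to the mRNAs being translated. OSGIN1, an oxidative stress-induced growth inhibitor (chromosome 16, 82556650 to 82556709), rose by 3.37 ± 0.28, from −3.48 ± 0.32 to −0.11 ± 0.44 (SD). SPP1, which encodes osteopontin, rose by 2.67 ± 0.28 with 2 of 3 vehicle arrays above background, and RET, a receptor tyrosine kinase of sympathetic neurons, rose by 2.44 ± 0.47, also with 2 of 3. CHRDL2, a secreted antagonist of bone morphogenetic proteins, was at least 17.1-fold higher and PDGFRL at least 4.62-fold higher. COL1A2, a type I collagen chain, fell by 3.62 ± 0.58, the pseudogene POM121L8P fell by 3.63 ± 0.52 and CDKN1A, the cyclin-dependent kinase inhibitor p21, fell by 1.46 ± 0.30. MYCN, the amplified oncogene of many neuroblastomas, stood at 0.01 ± 0.12 (adjusted p = 0.98), and CYP1A1 at −0.02 ± 0.28 (adjusted p = 0.97).

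Some genes of the oxidative stress response rose with isorhamnetin. Of the 22 measured NRF2 target genes, 7 rose, 0 fell and 15 did not pass (8 rose adjusted over the list alone), with a list test adjusted p of 4.41e-07 and adjusted p = 0.192 with an estimated correlation. Besides OSGIN1, NQO1, a quinone reductase, rose by 2.20 ± 0.31 with 1 of 3 vehicle arrays above background, and SRXN1, which restores oxidised peroxiredoxins, rose by 0.99 ± 0.12. HMOX1, a heme oxygenase, stood at 0.86 ± 0.37 (adjusted p = 0.17, 0.023 with the slide block).

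Some ATF4 targets fell. Among 24 measured ATF4 and amino acid response genes, 7 fell, 0 rose and 17 did not pass (9 fell adjusted over the list alone), with a list test adjusted p of 3.49e-05 and adjusted p = 0.192 with an estimated correlation. WARS1, the tryptophanyl-tRNA synthetase, fell by 0.88 ± 0.13, CTH, an enzyme of cysteine synthesis, fell by 0.63 ± 0.12, and PSAT1, an enzyme of serine synthesis, fell by 0.56 ± 0.09.

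Members of 3 further lists rose more often than they fell. Of 22 measured NOTCH, BMP and TGF-beta response genes, 5 rose and 2 fell (8 and 3 adjusted over the list alone, 15 and 3 with the slide block; adjusted p = 0.000417, adjusted p = 0.206 with an estimated correlation). BAMBI rose by 1.19 ± 0.26, a call lost without any of 3 arrays (highest adjusted p = 0.0566), HEY1 by 0.77 ± 0.16 and HEYL by 0.66 ± 0.13. Of 16 measured genes of mesenchymal neuroblastoma cells, 6 rose and 1 fell (8 and 1 adjusted over the list alone, 8 and 1 with the slide block; adjusted p = 0.00221, adjusted p = 0.495 with an estimated correlation). TGFBI, an extracellular matrix protein, rose by 1.97 ± 0.22, YAP1, a Hippo pathway coactivator, rose by 0.89 ± 0.11, and IFI16, an innate DNA sensor, fell by 1.84 ± 0.19. Of 23 measured FOXO and PI3K-responsive genes, 7 rose and 1 fell (8 and 2 adjusted over the list alone, 8 and 2 with the slide block; adjusted p = 0.0112, adjusted p = 0.488 with an estimated correlation). PIK3R1, a regulatory subunit of PI3K, rose by 1.5 ± 0.28 and TXNIP fell by 0.95 ± 0.14, while GADD45B was at least 1.75-fold higher on its brightest probe but stood at 0.20 (adjusted p = 0.52) where probes had to be above background on all 12 arrays.

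Proliferation and ribosome lists were lower as sets, with few members past the threshold. Of 31 measured G1/S and DNA replication genes, 5 fell and 0 rose (5 adjusted over the list alone; adjusted p = 0.00468, adjusted p = 0.554 with an estimated correlation). RRM2, a ribonucleotide reductase subunit, fell by 0.67 ± 0.10 and CCND3, a D-type cyclin, fell by 0.66 ± 0.09. Of 30 MYC and MYCN target genes, 2 fell (1 adjusted over the list alone; adjusted p = 0.0112, adjusted p = 0.495 with an estimated correlation). LDHA, lactate dehydrogenase, fell by 0.44 ± 0.08 and ODC1, of polyamine synthesis, fell by 0.45 ± 0.13, a call that ended without any of 10 of the 12 arrays (highest adjusted p = 0.165). None of the 79 ribosomal protein genes passed (0 adjusted over the list alone), although 75 had values under 0 and the list median was −0.16 (adjusted p = 0.000499, adjusted p = 0.738 with an estimated correlation); quantile normalization moved that median to −0.03 (adjusted p = 0.243).

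Of the remaining lists that passed, p53 target genes had 1 member up and 6 down of 22 (1 and 9 adjusted over the list alone; adjusted p = 0.0345, 0.0703 with the slide block, and adjusted p = 0.495 with an estimated correlation). Endoplasmic reticulum unfolded protein response genes had 0 up and 4 down of 22 (5 down adjusted over the list alone; adjusted p = 0.0243, adjusted p = 0.495 with an estimated correlation). Glycolysis and hypoxia genes had 1 up and 4 down of 28 (1 and 9 adjusted over the list alone; adjusted p = 0.0343, adjusted p = 0.488 with an estimated correlation). Oxidative phosphorylation genes had 0 up and 2 down of 32 (0 adjusted over the list alone; adjusted p = 0.0112, adjusted p = 0.524 with an estimated correlation). G2/M and mitosis genes had 0 up and 2 down of 32 (1 adjusted over the list alone; adjusted p = 0.0436, adjusted p = 0.738 with an estimated correlation), and cholesterol synthesis genes had 0 up and 1 down of 24 (1 adjusted over the list alone; adjusted p = 0.0436, adjusted p = 0.738 with an estimated correlation).

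In all, 805 genes rose and 905 fell with isorhamnetin, of which 1705 had the same sign on all 3 slides, and with the slide block 2309 rose and 2976 fell. Without isorhamnetin replicate 1 the total of 1710 genes was 800, and quantile normalization lowered the number of lists past the test from 14 to 6, ending the calls of the MYC, ribosomal protein, G2/M, p53, unfolded protein response, cholesterol, glycolysis and oxidative phosphorylation lists. The median moved from −0.14 to −0.02 in the MYC list, from −0.16 to −0.03 in the ribosomal protein list, from −0.18 to −0.05 in the oxidative phosphorylation list and from −0.14 to −0.07 in the G2/M list. It moved from −0.18 to −0.12 in the cholesterol list, from −0.23 to −0.16 in the glycolysis list and from −0.27 to −0.21 in the unfolded protein response list (adjusted p = 0.0901), and stayed at −0.24 in the p53 list (adjusted p = 0.0702).

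13cRA was compared with vehicle to read the response to the retinoid alone. SPP1 (chromosome 4, 89122944 to 89123003) rose by 8.89 ± 0.28, from −5.61 ± 0.21 to 3.27 ± 0.37 (SD), with 2 of 3 vehicle arrays above background. ENPP2, the lysophospholipase D autotaxin, rose by 8.28 ± 0.42, and CCN3, a matricellular protein, rose by 6.11 ± 0.12. GDF10, a ligand of the bone morphogenetic protein family, was at least 194-fold higher, RFPL1 at least 201-fold and H19, an imprinted long noncoding RNA, at least 37.2-fold. Of the falls, NELL1 was at least 15.8-fold lower, SEMA3D, a secreted semaphorin, at least 9.80-fold lower and the kinase gene DCLK3 at least 9.45-fold lower, while IGFBP5, an IGF-binding protein, fell by 3.42 ± 0.47 with 2 of 3 13cRA arrays above background on its brightest probe.

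Most measured retinoid target genes rose. Of 18 measured retinoic acid response genes, 11 rose, 0 fell and 7 did not pass (15 rose adjusted over the list alone), with a list test adjusted p of 2.69e-14 and adjusted p = 0.00166 with an estimated correlation, but 0.0816 with the slide block as well. RARB, a retinoic acid receptor (chromosome 3, 25613626 to 25613685), was at least 10.6-fold higher and DHRS3, a retinaldehyde reductase, at least 16.2-fold higher. CYP26A1, the retinoic acid hydroxylase, was at least 1.2-fold higher with 1 of 3 13cRA arrays above background, and did not pass (adjusted p = 0.055, 0.013 with the slide block). Of 21 measured HOX and TALE homeobox genes, which set position along the body axis, 6 rose and 0 fell (9 rose adjusted over the list alone; adjusted p = 1.08e-05, adjusted p = 0.0803 with an estimated correlation). HOXC5 rose by 1.80 ± 0.13 and HOXD8 by 0.96 ± 0.13.

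Of 17 measured adrenergic core transcription factors, which specify the sympathetic identity of neuroblastoma cells, 7 fell and 2 rose (7 and 2 adjusted over the list alone; adjusted p = 0.0377, adjusted p = 0.311 with an estimated correlation). ISL1 fell by 1.76 ± 0.18 and HAND1 fell by 1.39 ± 0.20, while MYCN stood at −0.13 ± 0.12 (adjusted p = 0.66). RET rose by 2.13 ± 0.47, a call that was lost without 1 of the 12 arrays (adjusted p = 0.0524).

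Some targets of the aryl hydrocarbon receptor (AHR), a ligand-activated transcription factor, rose with 13cRA. Of 10 measured AHR target genes, 4 rose, 1 fell and 5 did not pass (4 and 2 adjusted over the list alone; adjusted p = 0.00998, adjusted p = 0.311 with an estimated correlation). CYP1A1, a monooxygenase that oxidises polycyclic aromatics (chromosome 15, 72799615 to 72799674), rose by 5.41 ± 0.28 (adjusted p = 7.1e-07), and CYP1B1 rose by 1.41 ± 0.17. AHRR, the repressor of AHR (chromosome 5, 491030 to 491089), was at least 9.76-fold higher. The mRNA of AHR itself, named after its value was seen, was also higher. It stood at −1.40 ± 0.43 (SD) with 13cRA, with 3 of 3 arrays above background. With vehicle it stood at −6.08 ± 0.61, with 0 of 3.

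Of 24 measured fatty acid synthesis and lipid genes, 4 rose and 0 fell (5 rose and 1 fell adjusted over the list alone; adjusted p = 0.0424, adjusted p = 0.604 with an estimated correlation). PPARG, a nuclear receptor of lipid storage, rose by 1.76 ± 0.18, ACSL3 by 1.17 ± 0.12 and ACSL4, another acyl-CoA synthetase, by 1.06 ± 0.25, the last call being lost without any of 3 arrays (highest adjusted p = 0.0763). Of 23 FOXO and PI3K-responsive genes, 5 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0108, adjusted p = 0.311 with an estimated correlation). GADD45B was at least 4.01-fold higher on its brightest probe and FOXO3 rose by 0.74 ± 0.12. Of 30 MYC and MYCN target genes, only LDHA passed (1 adjusted over the list alone), which fell by 0.47 ± 0.08, with a list test adjusted p of 0.0118 and adjusted p = 0.604 with an estimated correlation. The list of endoplasmic reticulum unfolded protein response genes, with 0 up and 3 down of 22 (3 down adjusted over the list alone), had an adjusted p of 0.0557 (0.0129 with the slide block) and adjusted p = 0.661 with an estimated correlation.

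In all, 687 genes rose and 938 fell with 13cRA, all 1625 with the same sign on the 3 slides, and with the slide block 1605 rose and 2231 fell. Quantile normalization ended the calls of the adrenergic (adjusted p = 0.0686), MYC (adjusted p = 0.0733) and lipid (adjusted p = 0.0686) lists, whose medians went from −0.15, −0.17 and 0.09 to −0.11, −0.13 and 0.11.

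**Figure D1:**
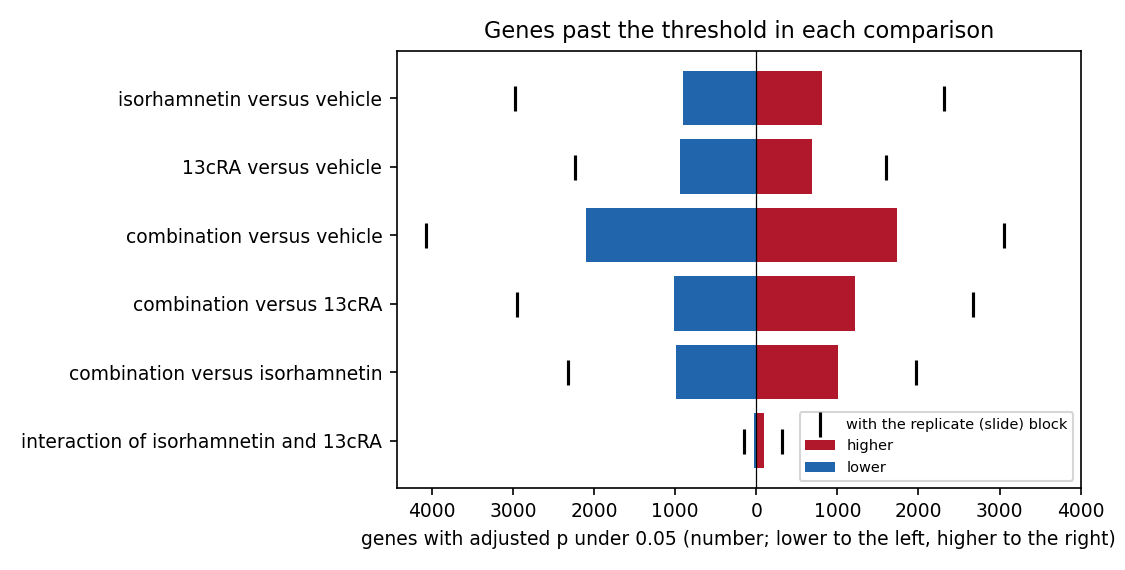
Number of genes with an adjusted p under 0.05 in each comparison (bars, genes lower to the left and higher to the right), with black marks for the counts of the fit with the replicate (slide) block. The combination versus vehicle had the most calls of the 6 comparisons, 1735 higher and 2094 lower, and the interaction the fewest, 95 and 26.

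The combination was compared with vehicle to find what both agents together changed. SPP1 rose by 11.67 ± 0.28, from −5.61 ± 0.21 to 6.06 ± 0.55 (SD), with 2 of 3 vehicle arrays above background. ENPP2 rose by 8.09 ± 0.42, TXK, a Tec-family kinase, was at least 75-fold higher, CCBE1, a secreted factor of lymphatic growth, at least 93.5-fold, DHRS3 at least 55.1-fold and RARB at least 28.6-fold. POM121L8P, with 2 of 3 combination arrays above background, fell by 7.64 ± 0.52, COL1A2 fell by 4.80 ± 0.58, the homeobox gene SP8 was at least 12.3-fold lower and SEMA3D at least 10.9-fold lower. RET rose by 4.72 ± 0.47 and MYCN stood at −0.09 ± 0.12 (adjusted p = 0.66).

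Of 18 measured retinoic acid response genes, 14 rose and 0 fell (15 rose adjusted over the list alone; adjusted p = 3.70e-12, adjusted p = 0.00295 with an estimated correlation, but 0.0781 with the slide block as well). CYP26A1 was at least 6.69-fold higher, and HIC1, a transcriptional repressor, rose by 3.14 ± 0.16. Of 21 measured HOX and TALE homeobox genes, 14 rose and 0 fell (14 rose adjusted over the list alone; adjusted p = 5.45e-09, adjusted p = 0.0221 with an estimated correlation and 0.0285 with the slide block as well). HOXC5 rose by 2.99 ± 0.13. HOXB3 was at least 4.21-fold higher on its brightest probe, but stood at −0.06 when dim probes were kept and another probe represented the gene.

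Immediate early and MAPK feedback genes, which are induced by growth factor signalling through ERK, rose in the combination. Of 20 measured members, 16 rose, 3 fell and 1 did not pass (16 and 3 adjusted over the list alone), with a list test adjusted p of 5.45e-09 and adjusted p = 0.0947 with an estimated correlation. FOS (chromosome 14, 74817967 to 74818026) was at least 18.1-fold higher, JUN, its dimer partner, rose by 3.1 ± 0.16 and MYC rose by 2.46 ± 0.18. The list median was 1.06, or 0.89 with values below background raised to the lowest signal above it.

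**Figure D2:**
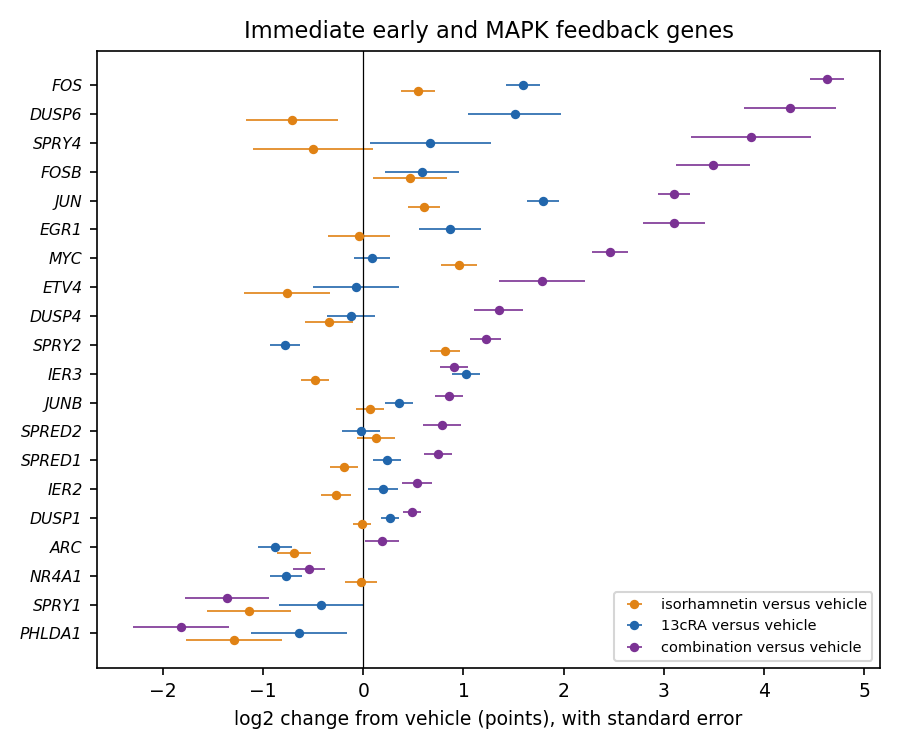
Fitted log2 change from vehicle (points) with its standard error (bars) of the 20 measured immediate early and MAPK feedback genes, for isorhamnetin, 13cRA and the combination, 3 arrays per group. FOS, at 4.63 in the combination, and FOSB, ETV4 and SPRY4 were above background on 0 of 3 vehicle arrays, so that their points depend on the lowest signals; JUN stood at 3.1.

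Of 22 measured NOTCH, BMP and TGF-beta response genes, 14 rose and 3 fell (15 and 4 adjusted over the list alone; adjusted p = 4.90e-05, adjusted p = 0.103 with an estimated correlation). HES1, a Notch effector, rose by 5.23 ± 0.32, SKIL, a repressor of SMAD signalling, by 2.22 ± 0.12 and LTBP3, a TGF-beta binding protein, by 1.92 ± 0.14. Of 23 FOXO and PI3K-responsive genes, 10 rose and 2 fell (14 and 4 adjusted over the list alone; adjusted p = 0.000525, adjusted p = 0.131 with an estimated correlation). GADD45B was at least 29.9-fold higher on its brightest probe, FOXO3 rose by 1.43 ± 0.12 and PIK3IP1, an inhibitor of PI3K, was at least 4.87-fold higher. Of 22 NRF2 target genes, 10 rose and 0 fell (10 adjusted over the list alone; adjusted p = 9.04e-06, adjusted p = 0.103 with an estimated correlation), among them OSGIN1 at 3.63 ± 0.28, SRXN1 at 1.39 ± 0.12 and TXNRD1, thioredoxin reductase, at 0.94 ± 0.12.

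Cell cycle and growth lists were lower. Of 31 G1/S and DNA replication genes, 14 fell and 0 rose (14 adjusted over the list alone; adjusted p = 2.78e-05, adjusted p = 0.305 with an estimated correlation). RRM2 fell by 0.82 ± 0.10, E2F8, a repressor of the E2F family, fell by 0.76 ± 0.11 and CCND3 fell by 0.62 ± 0.09, while CCND1 stood at −0.01 ± 0.12 (adjusted p = 0.97). Of 30 MYC and MYCN target genes, 11 fell and 0 rose (11 adjusted over the list alone; adjusted p = 9.49e-05, adjusted p = 0.25 with an estimated correlation). LDHA fell by 0.77 ± 0.08, AMD1 fell by 0.60 ± 0.09 and PPAN fell by 0.52 ± 0.09. Among the other lists that passed, unfolded protein response genes had 1 up and 10 down of 22 (1 and 10 adjusted over the list alone; adjusted p = 0.00247, adjusted p = 0.291 with an estimated correlation), and ATF4 and amino acid response genes had 2 up and 9 down of 24 (2 and 10 adjusted over the list alone; adjusted p = 0.00484, adjusted p = 0.25 with an estimated correlation). Genes of mesenchymal neuroblastoma cells had 7 up and 2 down of 16 (7 and 2 adjusted over the list alone; adjusted p = 0.0179, adjusted p = 0.487 with an estimated correlation).

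The ribosomal protein, cholesterol, G2/M and glycolysis lists also passed in the combination (adjusted p = 0.0026, 0.0179, 0.0279 and 0.0382), but each call ended with quantile normalization (adjusted p = 0.175, 0.066, 0.125 and 0.0973). Their medians went from −0.18, −0.34, −0.20 and −0.24 to −0.05, −0.24, −0.09 and −0.19. With the estimated correlation the values were adjusted p = 0.612, 0.567, 0.573 and 0.291. Members down were 3 of 79, 6 of 24, 6 of 32 and 8 of 28 (0, 6, 5 and 13 adjusted over the list alone), and members up were 0, 0, 0 and 2 (0, 0, 0 and 3 adjusted over the list alone). With the slide block, oxidative phosphorylation genes (0 up and 2 down of 32, 0 adjusted over the list alone) went from an adjusted p of 0.0931 to 0.0397 and fatty acid and lipid genes (3 up and 2 down of 24, the same counts adjusted over the list alone) from 0.0931 to 0.0342, with adjusted p = 0.567 and 0.487 with an estimated correlation.

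In all, 1735 genes rose and 2094 fell in the combination, 3816 of them with the same sign on the 3 slides, and with the slide block 3054 rose and 4073 fell. Median scaling shifted the median of all genes to −0.115, against −0.048, and then 1369 genes rose and 2374 fell.

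Combination and 13cRA arrays were compared to see what isorhamnetin added to the retinoid. S1PR1, a receptor for sphingosine phosphate (chromosome 1, 101478909 to 101478968), was at least 9.09-fold higher, HAPLN1, a link protein of the extracellular matrix, at least 18.7-fold and GASK1B at least 13.6-fold, each above background on all 3 combination arrays and on 0 of 9 others. ADRA1B, an alpha-adrenergic receptor, rose by 5.02 ± 0.33, and the homeobox gene MSX2, with 1 of 3 13cRA arrays above background, rose by 4.82 ± 0.81. CYP1A1 fell by 3.99 ± 0.28, from 0.38 ± 0.41 to −3.61 ± 0.61 (SD), with −3.90, −3.46 and −4.60 on the 3 slides. AHRR was at least 10.2-fold lower and MLC1, a membrane protein of astrocytes, at least 3.39-fold lower, though MLC1 stood at 0.01 with another background correction.

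Of 10 measured AHR target genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone; adjusted p = 0.0280, 0.108 with the slide block, and adjusted p = 0.34 with an estimated correlation), and CYP1B1 fell by 1.03 ± 0.17. Of 18 retinoic acid response genes, 7 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.00064, adjusted p = 0.055 with an estimated correlation). CYP26B1, a retinoic acid hydroxylase, rose by 3.69 ± 0.32, HIC1 by 2.12 ± 0.16, DHRS3 by 1.76 ± 0.38 and RARB by 1.44 ± 0.12. Of 21 HOX and TALE genes, 9 rose and 0 fell (10 rose adjusted over the list alone; adjusted p = 3.32e-06, adjusted p = 0.055 with an estimated correlation). HOXC5 rose by 1.19 ± 0.13 and HOXC8 by 0.95 ± 0.10.

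Of 20 immediate early and MAPK feedback genes, 14 rose and 0 fell (14 and 1 adjusted over the list alone; adjusted p = 1.57e-09, adjusted p = 0.055 with an estimated correlation). FOS rose by 3.05 ± 0.17, MYC by 2.37 ± 0.18 and SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, by 2.00 ± 0.15. Of 22 NRF2 target genes, 9 rose and 0 fell (10 rose adjusted over the list alone; adjusted p = 6.22e-07, adjusted p = 0.0574 with an estimated correlation). OSGIN1 rose by 3.31 ± 0.28, SRXN1 by 1.13 ± 0.12 and GSR, glutathione reductase, by 0.59 ± 0.08. Of 22 NOTCH, BMP and TGF-beta response genes, 14 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 3.32e-06, adjusted p = 0.055 with an estimated correlation). HES1 rose by 2.63 ± 0.32, LTBP3 by 1.32 ± 0.14 and TGFB1 by 1.23 ± 0.12. Of 16 mesenchymal genes, 6 rose and 2 fell (9 and 2 adjusted over the list alone; adjusted p = 0.000786, adjusted p = 0.34 with an estimated correlation). COL3A1, a fibrillar collagen, was at least 4.85-fold higher, CD44, a hyaluronan receptor, rose by 0.87 ± 0.11 and IFI16 fell by 1.80 ± 0.19.

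Of 31 G1/S and DNA replication genes, 9 fell and 1 rose (15 and 1 adjusted over the list alone; adjusted p = 3.43e-05, adjusted p = 0.341 with an estimated correlation). CCNE2, an E-type cyclin, fell by 0.94 ± 0.16, RRM2 fell by 0.77 ± 0.10 and CDC45, a replication factor, fell by 0.48 ± 0.08. Of 24 cholesterol synthesis genes, 3 fell and 0 rose (3 adjusted over the list alone; adjusted p = 0.00331, adjusted p = 0.572 with an estimated correlation). SC5D fell by 0.60 ± 0.10, EBP fell by 0.45 ± 0.09 and ACAT2 fell by 0.63 ± 0.17, which had an adjusted p of 0.0686 with quantile normalization and lost its call without any of 3 arrays (highest adjusted p = 0.106). FOXO and PI3K-responsive genes had 7 up and 1 down of 23 (9 and 1 adjusted over the list alone; adjusted p = 0.0280, 0.0799 with the slide block, and adjusted p = 0.34 with an estimated correlation). ATF4 and amino acid response genes had 0 up and 7 down of 24 (9 down adjusted over the list alone; adjusted p = 0.0101, adjusted p = 0.34 with an estimated correlation).

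The MYC, G2/M, ribosomal protein, unfolded protein response, glycolysis and oxidative phosphorylation lists passed as well (adjusted p = 0.0101, 0.0186, 0.0264, 0.0280, 0.0314 and 0.0314), and each call ended with quantile normalization (adjusted p = 0.0633, 0.0633, 0.311, 0.0628, 0.0701 and 0.364). Their medians went from −0.15, −0.16, −0.10, −0.24, −0.14 and −0.09 to −0.11, −0.12, −0.04, −0.18, −0.11 and −0.04. With an estimated correlation they had adjusted p = 0.42, 0.68, 0.825, 0.466, 0.34 and 0.572. Members down were 3 of 30, 3 of 32, 0 of 79, 3 of 22, 5 of 28 and 2 of 32, and 0 of each rose (0, 2, 0, 3, 5 and 0 down adjusted over the list alone).

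In all, 1220 genes were higher and 1014 lower in the combination than with 13cRA, 2232 of 2234 with the same sign on the 3 slides, and with the slide block 2668 were higher and 2948 lower. Without 13cRA replicate 2 the total was 1410.

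**Figure D3:**
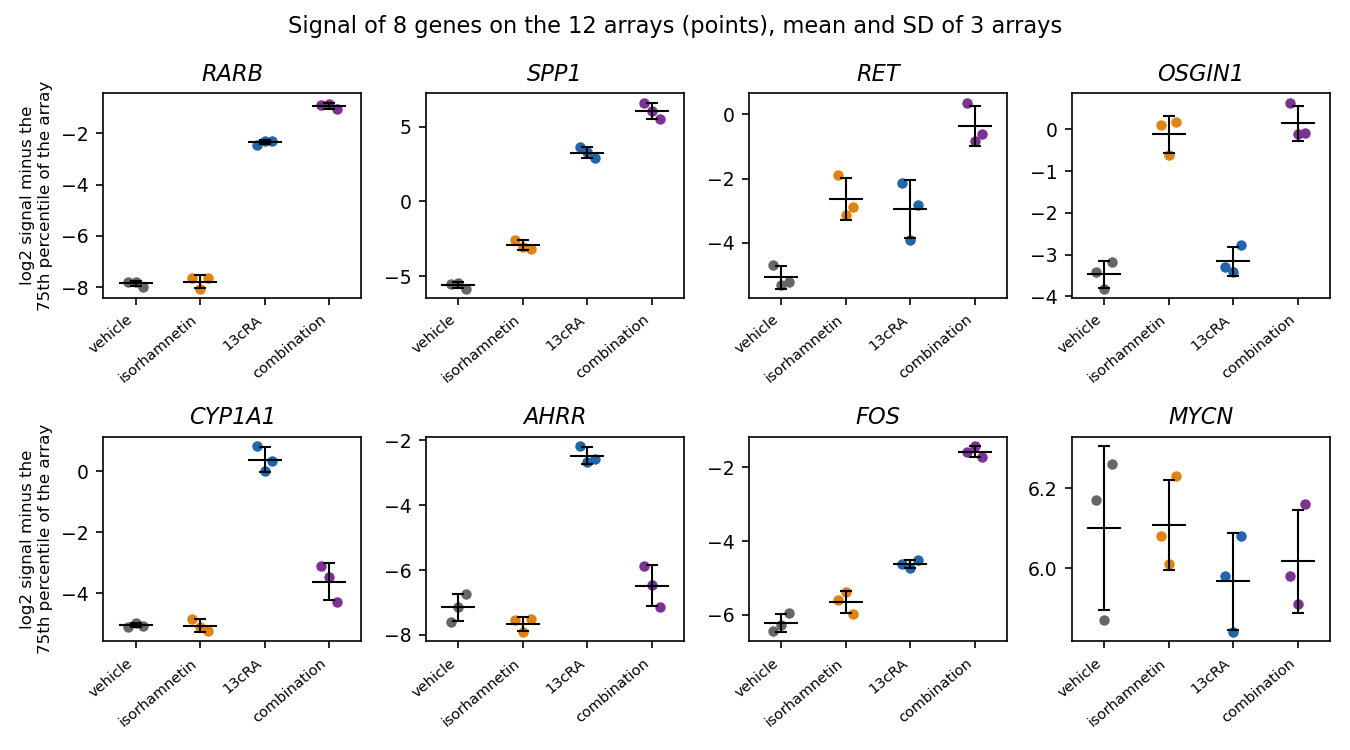
Signal of 8 genes on the 12 arrays as log2 signal minus the 75th percentile of the array (points), with the mean and SD of the 3 arrays of each group (lines). CYP1A1 was at 0.38 with 13cRA and at −3.61 in the combination, RARB at −2.35 and −0.91, and the 4 group means of MYCN lay between 5.97 and 6.11.

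Combination and isorhamnetin arrays were compared to see what 13cRA added to the flavonoid. SPP1 rose by 9 ± 0.28, ENPP2 by 7.81 ± 0.42 and RFPL1, with 1 of 3 isorhamnetin arrays above background, by 7.46 ± 0.10, while DHRS3 was at least 55.3-fold higher and ARSI, a sulfatase, at least 49.6-fold. SEMA3D was at least 22.1-fold lower and SP8 at least 14.1-fold lower. SLC6A2, the noradrenaline transporter, fell by 4.58 ± 0.53 with 1 of 3 combination arrays above background, NELL1, also with 1 of 3, fell by 5.38 ± 0.62, and ADRA2A, an alpha-adrenergic receptor, fell by 4.11 ± 0.34.

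Of 18 retinoic acid response genes, 15 rose and 0 fell (15 adjusted over the list alone; adjusted p = 5.62e-17, adjusted p = 0.000889 with an estimated correlation). RARB was at least 27.1-fold higher and CYP26A1 at least 6.33-fold. Of 20 immediate early and MAPK feedback genes, 16 rose and 0 fell (17 and 1 adjusted over the list alone; adjusted p = 7.63e-14, adjusted p = 0.0277 with an estimated correlation). DUSP6, a phosphatase that inactivates ERK, rose by 4.97 ± 0.46, JUN rose by 2.49 ± 0.16, and FOS, with 1 of 3 isorhamnetin arrays above background, rose by 4.08 ± 0.17. Of 21 HOX and TALE genes, 12 rose and 0 fell (12 adjusted over the list alone; adjusted p = 3.08e-09, adjusted p = 0.0202 with an estimated correlation). HOXC5 rose by 2.79 ± 0.13. Of these 3 lists, only HOX and TALE genes also passed with an estimated correlation and the slide block together (adjusted p = 0.0281, against 0.0566 for retinoic acid response and 0.128 for immediate early genes).

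Of 17 adrenergic core transcription factors, 8 fell and 1 rose (9 and 3 adjusted over the list alone; adjusted p = 0.0101, adjusted p = 0.191 with an estimated correlation). ISL1 fell by 3.23 ± 0.18 and KLF7 rose by 1.18 ± 0.11. Of 31 G1/S and DNA replication genes, 4 fell and 0 rose (4 adjusted over the list alone; adjusted p = 0.0101, adjusted p = 0.546 with an estimated correlation). E2F2 fell by 0.64 ± 0.14 and E2F8 fell by 0.60 ± 0.11. Of 30 MYC and MYCN target genes, 3 fell and 0 rose (2 adjusted over the list alone; adjusted p = 0.0132, adjusted p = 0.494 with an estimated correlation). AMD1 fell by 0.42 ± 0.09 and LDHA fell by 0.33 ± 0.08, a call lost without any of 3 arrays (highest adjusted p = 0.0608). Of 22 NOTCH, BMP and TGF-beta response genes, 5 rose and 4 fell (9 and 4 adjusted over the list alone; adjusted p = 0.0184, adjusted p = 0.366 with an estimated correlation). HES1 rose by 4.65 ± 0.32 and SKIL by 1.99 ± 0.12. Of 23 FOXO and PI3K-responsive genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.0184, adjusted p = 0.366 with an estimated correlation). GADD45B rose by 4.10 ± 0.25 and CITED2 fell by 0.86 ± 0.11. Of 24 fatty acid synthesis and lipid genes, 3 rose and 0 fell (3 adjusted over the list alone; adjusted p = 0.0184, adjusted p = 0.372 with an estimated correlation). Unfolded protein response genes, with 0 up and 2 down of 22 (2 down adjusted over the list alone), had an adjusted p of 0.0682, 0.00937 with the slide block, and adjusted p = 0.546 with an estimated correlation.

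In all, 1012 genes were higher and 990 lower in the combination than with isorhamnetin, all 2002 with the same sign on the 3 slides, and with the slide block 1975 were higher and 2324 lower.

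The interaction, the change in the combination beyond the sum of the changes with each agent, was tested because the series was designed to look for synergistic effects. CYP1A1 was lower than the sum by 3.96 ± 0.39 on the log2 scale, with a fitted interaction of −3.96 (adjusted p = 0.0012), and TIPARP, an AHR-induced ADP-ribosyltransferase, had −2.26 ± 0.27 (adjusted p = 0.0031) and CYP1B1 −1.42 ± 0.24 (adjusted p = 0.021), a call lost without any of 4 arrays (highest adjusted p = 0.0606). ADRA1B was higher than the sum, at 4.51 ± 0.47 (adjusted p = 0.0014), CYP26B1 at 3.09 ± 0.45 (adjusted p = 0.011) and HIC1 at 1.88 ± 0.23 (adjusted p = 0.0036). For HAPLN1, S1PR1 and GASK1B the call rests on a signal above background in the combination and in no other group. RET, at 0.15 ± 0.67 (adjusted p = 1), and MYCN, at 0.04 ± 0.17 (adjusted p = 1), did not pass.

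Of 20 immediate early and MAPK feedback genes, 7 were higher than the sum and 0 lower (14 higher adjusted over the list alone; adjusted p = 1.98e-25, adjusted p = 0.0058 with an estimated correlation). ARC, an immediate early gene of neurons, had 1.76 ± 0.24 and SPRY2 1.18 ± 0.21. ARC stood at −3.20 with vehicle, −3.89 with isorhamnetin, −4.08 with 13cRA and −3.01 in the combination. Its interaction thus comes mostly from lower values with each agent alone, and the combination was near vehicle. SPRY2 was lower with 13cRA (−3.38, −3.53 and −3.26) than with vehicle (−2.65, −2.60 and −2.58), and higher in the combination (−1.09, −1.39 and −1.70). Of 18 retinoic acid response genes, 4 were higher and 0 lower (6 higher adjusted over the list alone; adjusted p = 1.83e-08, adjusted p = 0.0058 with an estimated correlation). Of 21 HOX and TALE genes, 4 were higher and 0 lower (6 higher adjusted over the list alone; adjusted p = 9.35e-07, adjusted p = 0.0355 with an estimated correlation), with HOXC5 at 1.00 ± 0.18 and HOXC8 at 0.81 ± 0.15. The calls of HOXC5, HOXC8 and SPRY2 were lost without 9, 10 and 10 single arrays in turn, with adjusted p of at most 0.0969, 0.0931 and 0.0945. With the slide block and an estimated correlation together, the immediate early, retinoic acid and HOX lists had adjusted p of 0.0534, 0.164 and 0.0534.

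Of 10 AHR target genes, 4 were lower than the sum and 1 higher (4 and 1 adjusted over the list alone; adjusted p = 0.00104, 0.0524 with the slide block, and adjusted p = 0.173 with an estimated correlation); the list median was 0.06 and the mean −0.83. Of 22 NOTCH, BMP and TGF-beta response genes, 0 passed (3 higher and 1 lower adjusted over the list alone; adjusted p = 0.00104, adjusted p = 0.173 with an estimated correlation), with HES1 at 2.05 ± 0.46 (adjusted p = 0.081, 0.0074 with the slide block). Of 31 G1/S and DNA replication genes, 0 passed (1 higher adjusted over the list alone; adjusted p = 0.0442, adjusted p = 0.92 with an estimated correlation). ATF4 and amino acid response genes, with 0 of 24 past the threshold (0 adjusted over the list alone), had an adjusted p of 0.189, 0.0108 with the slide block, and adjusted p = 0.851 with an estimated correlation.

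In all, 95 genes were higher and 26 lower than the sum, 320 and 155 with the slide block, and 29 of the 121 had at least 1 group with no array above background. Without isorhamnetin replicate 1 the count was 62, and without 1 replicate number in all groups it was between 0 and 35.

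**Figure D4:**
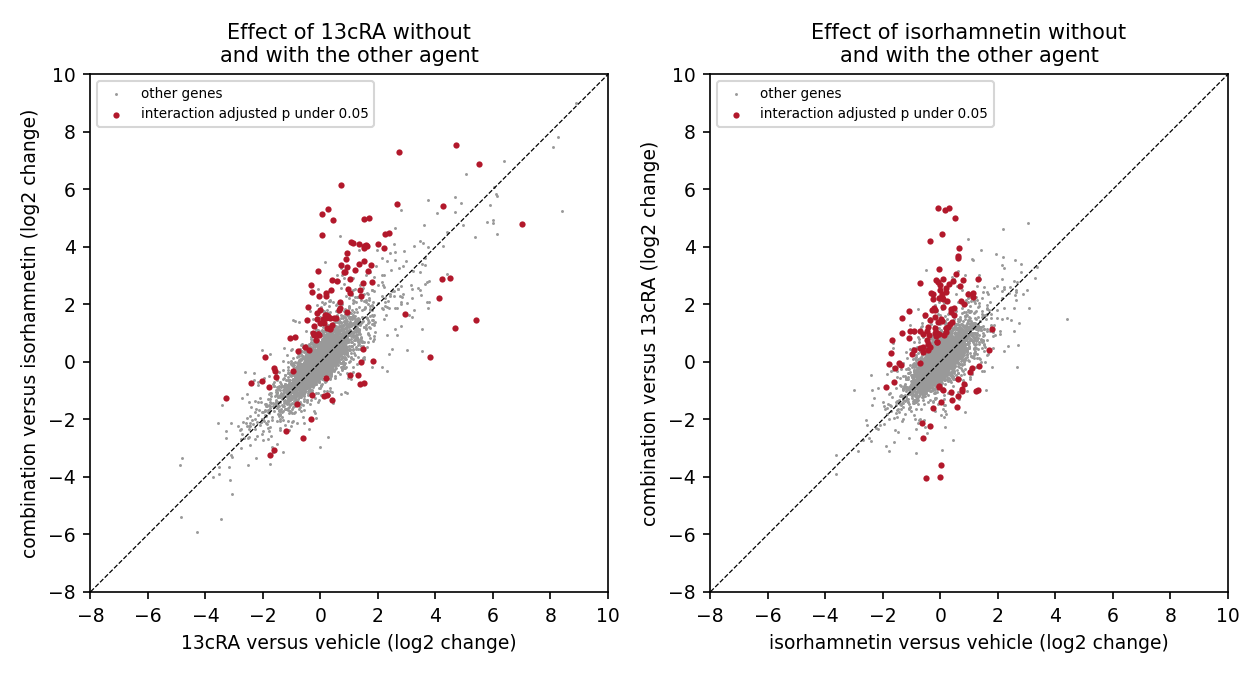
Log2 change of each gene with 13cRA without isorhamnetin (x axis) and with it (y axis), left, and with isorhamnetin without 13cRA (x axis) and with it (y axis), right; red points are the 121 genes past the interaction threshold and the dashed line marks equal change. Across 14330 genes r was 0.82 on the left and 0.68 on the right.

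Effects of each agent with and without the other were set side by side from groups that share no array. Across the 14330 genes, the change with 13cRA alone and the change from isorhamnetin to the combination had r = 0.82 and Spearman's rho = 0.70, with the same sign in 75.6% of genes. For isorhamnetin alone and the change from 13cRA to the combination, r was 0.68 and rho 0.72, with the same sign in 79.5%. Genes are not independent replicates, so no p is given.

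Calls against vehicle share the 3 vehicle arrays, which are too few to split. Of the 3829 genes called in the combination, 1177 were also called in the same direction with 13cRA and 1135 with isorhamnetin. Independent calls would give 83 up and 137 down for 13cRA, against 533 and 644, and 98 and 132 for isorhamnetin, against 491 and 644. Simulated unchanged groups sharing the vehicle arrays gave 0, but unchanged groups hold hardly any calls. This value therefore cannot show how far the shared arrays raise the overlap. The changes of such groups had r = 0.50 and a covariance of 0.023. Observed against the combination were r = 0.74 and 0.292 for 13cRA, and r = 0.50 and 0.144 for isorhamnetin. Isorhamnetin and 13cRA shared 86 genes up and 131 down, against 38.6 and 59.2 from independent calls, and had 243 in opposite directions, against 96.1. The covariance of their changes was 0.011 (r = 0.05), against 0.023 from the shared vehicle arrays alone. Of the 3829 genes, 1720 were called with neither agent alone, and 38 of these passed the interaction test. The combination differed from vehicle and from each agent, in the same direction, in 353 genes up and 171 down, 739 and 726 with the slide block. A difference among the 4 groups was found in 4723 genes, and in 8906 with the slide block.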

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

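Of the tests in this part, those of the AHR mRNA level, general damping, handling or cycloheximide exposure and brightness, and the relabelings within slides, were chosen after related values had been seen; the other tests of explanations were written down after the patterns had been seen but before the values they measure.

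In the interaction test 121 genes differed between the effect of 13cRA without isorhamnetin and its effect with it, which is why they are listed here. Of 100 relabelings of the 12 arrays, the real one included, 2 gave at least as many genes. Of 100 that kept 1 array of each group on every slide, 6 did (5 with the slide block, where the real count was 475), with a highest other of 2091, so this comparison does not exclude chance. The 5 others all had interaction weights that followed a treatment, with correlations of −1, −1, 1, −0.67 and 0.67 with isorhamnetin or 13cRA, so they count effects of an agent at least in part. The highest of the free relabelings, 2545 genes, points to a structure of the samples: like that of 2091, its interaction weights had a correlation of −1 with the isorhamnetin treatment, so that it counted the effect of that agent. For the difference among the 4 groups, 1 of 100 relabelings, the real one, gave 4723 genes and the highest other 1297, and within slides also 1 of 100 with a highest other of 1871, so chance can be excluded there. For the pairwise contrasts, the 10 splits of 6 arrays are too few for a share under 0.05; the real split alone, 1 of 10, gave its count in each, and the highest other splits gave 0, 0, 1, 0 and 0 genes against 1710, 1625, 3829, 2234 and 2002.

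Of 10 AHR target genes, 4 rose with 13cRA and 4 were lower in the combination than with 13cRA. Combination minus 13cRA on the 3 slides was −3.90, −3.46 and −4.60 for CYP1A1 and −3.70, −3.80 and −4.58 for AHRR. It was −0.82, −0.90 and −1.17 for TIPARP and −1.19, −1.09 and −0.81 for CYP1B1. The interactions were −3.96, −3.52, −2.26 and −1.42 in that order. The median interaction of the list was 0.06 (list test adjusted p = 0.00104, 0.0524 with the slide block and 0.173 with an estimated correlation). TIPARP was also higher with isorhamnetin alone, at 2.43, 1.99 and 2.18 against 1.15, 0.94 and 0.63 with vehicle, so its interaction exceeds its fall. A lower level of AHR mRNA on polysomes is argued against. AHR, named after its value was seen, was higher there in the combination than with 13cRA by 1.36 ± 0.38 (adjusted p = 0.034, and at most 0.124 without 1 array). Neither total AHR mRNA nor AHR protein was analysed here, so their levels stay open. The fall was seen on each slide, the highest of the 12 values of these 4 genes on 3 slides being −0.81. However, these are genes past the threshold over the same slides, and 2232 of 2234 such genes had the same sign on all 3. The agreement is therefore no separate support against a single slide or array. Genes that rose over 2-fold with 13cRA on 2 slides had medians of −0.10, −0.06 and −0.16 between the combination and 13cRA on the slide left out. Their mean was −0.11 (SE 0.03, 3 slides), and all genes had medians of 0, −0.05 and −0.03 there. Across all genes, the 13cRA effect with isorhamnetin had a slope of 1.15 on that without it (total least squares). These values argue against a general damping of the 13cRA response as the account of the larger falls of the 4 genes. A small contribution stays open. Of 18 retinoic acid response genes 7 rose and 1 fell from 13cRA to the combination over all arrays, with a median of 0.37. An action of isorhamnetin on AHR or on the breakdown of its ligands is a biological explanation that these data leave untested.

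Immediate early and MAPK feedback genes were higher in the combination than the sum of both agents, with a median interaction of 0.94. It was 0.70 with values below background raised to the lowest signal above it. The list test gave adjusted p = 0.0058 with an estimated correlation, and 0.0534 with the slide block as well. FOS had 2.5, ARC 1.76 and SPRY2 1.18. ARC in the combination was near vehicle (−3.01 against −3.20) and was lower with each agent alone, so its interaction is mostly no rise over vehicle. The list medians on the 3 slides were 1.26, 1.30 and 0.70, so the higher values were seen on each slide. However, the list had passed over the same slides, and all 121 genes past the interaction threshold had the same sign on the 3. This agreement is therefore no separate support against a single slide. Handling of the dishes or the exposure to cycloheximide, which can raise immediate early transcripts within minutes, could contribute. The feedback part of the list, which needs a lasting signal, had a median of 1.18 over 9 measured genes. Its SE of 0.57 measures the spread between those genes and not between replicates, so it cannot decide the question. On the slides the medians were 1.45, 1.51 and 0.83, but the whole list had passed on these same slides, and a part of handling stays open. All dishes received cycloheximide per the labels, and none of the arrays lacked it. A lasting ERK signal in cells given both agents stays open as a biological explanation and was not measured.

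Ribosomal protein mRNAs were lower on polysomes with isorhamnetin, with a list median of −0.16 over 79 genes, of which 0 passed alone (adjusted p = 0.000499, but 0.738 with an estimated correlation, which was 0.78). The list median minus that of all genes was −0.12 as reported, −0.12 with median scaling, −0.10 with normexp as planned and −0.03 with quantile normalization. Its size thus depends on the choice of quantile normalization. A factor common to a whole array cancels in this difference, so the part of the scaling of the arrays stays open. A trend with brightness may account for much of the lower median and stays open. Random lists of equally bright genes had a median of −0.12, against −0.16. Within slides the list median minus that of equally bright genes was −0.07, 0.01 and −0.05, a mean of −0.04 (SE 0.02). Lower ribosome loading and a lower mRNA level cannot be told apart, because 0 arrays of total RNA were analysed here.

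The other genes past the interaction threshold are given as values. With all 4 groups above background on every array, ADRA1B had 4.51, CYP26B1 3.09, HIC1 1.88, HOXC5 1.00 and HOXC8 0.81. In at least 1 group no array was above background for HAPLN1 at 5.44, S1PR1 at 5.11, GASK1B at 5.04, ARSI at 4.56, DHRS3 at 2.85, HOXB3 at 2.12, RARB at 1.36, H19 at −2.22 and MLC1 at −3.63, as for AHRR and FOS, so these fitted values depend on the lowest signals and are no measured sizes. Of the 12 arrays left out in turn, 11 ended the call of HOXB3, 10 each those of HOXC8 and SPRY2, 9 each those of HOXC5 and DHRS3, and 4 that of CYP1B1. The lists past the interaction test had medians of 0.50 (retinoic acid response genes), 0.32 (HOX and TALE homeobox genes), 0.41 (NOTCH, BMP and TGF-beta response genes) and −0.14 (G1/S and DNA replication genes), with adjusted p of 0.0058, 0.0355, 0.173 and 0.92 with an estimated correlation.

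Data outside the gene table also held a signal: of 4531 probes without a gene symbol that were above background, 702 passed between the combination and vehicle, 435 higher and 267 lower.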

How the results depend on the processing

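Alternatives named here were planned before the data were examined, except normexp without the spots described below, which was chosen after its result had been seen. Signal over background limits the genes that can be measured: 61.7% to 67.9% of spots were well above it. Of 239 calls of named genes, 30 were lost without some single array and 97 without some replicate number, 0 changed sign there, and 0 were lost with the replicate block. With normexp as planned 98 were lost and 2 reversed, and without the spots described below 13 and 0. Without a filter on dim probes 18 were lost and 2 reversed. Quantile normalization ended 7, and the deposited values ended 11 of the 185 calls they could test. Leaving out a replicate number leaves 2 arrays per group, and fewer arrays were tested.

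With normexp as planned, the counts were 96 (isorhamnetin), 399 (13cRA), 1740 (combination), 720 (combination versus 13cRA), 688 (combination versus isorhamnetin), 35 (interaction) and 1620 (4 groups). The effect correlations were 0.52 (13cRA) and 0.40 (isorhamnetin), the shared calls 284 and 66, the genes past vehicle and both agents 190, and the lists past the test 16 (combination versus isorhamnetin) and 12 (interaction). Reversed were oxidative phosphorylation genes in the combination versus isorhamnetin (−0.22) and in the interaction (−0.23), ribosomal proteins (−0.21) and translation factors (−0.23) in the interaction, and MLC1 against 13cRA (0.01) and in the interaction (0.29). On combination replicate 2, 10 spots had a local background above their signal (lowest difference −59448.8), and the fitted background was −1051.86 with them and 19.58 without, against 1.21 to 30.0 on the other arrays. Without such spots the counts were 1486, 1543, 3727, 2069, 1888, 131 and 4554, all within 1.5 times those reported, and MLC1 had −1.02 and −0.87. The share of calls that were higher also moved with normexp as planned, to 227 of 399 with 13cRA, 415 of 688 and 31 of 35.

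Without a filter on dim probes, isorhamnetin gave 1119 genes and the interaction 67, from more genes tested, and the correlations were 0.67 and 0.50; another probe stood for HOXB3, which then had −0.06 (combination versus vehicle) and −0.04 (versus isorhamnetin). With all 12 arrays above background the isorhamnetin correlation was 0.73, and 0.72 with the deposited values. Over genes called in either contrast the correlations were 0.86 and 0.72. The replicate block, which takes the slide differences out of the residual, gave 5285, 3836, 7127, 5616, 4299, 475 and 8906 genes, shared calls of 2624 and 3626, and 1465 genes past vehicle and both agents. A 2-fold minimum left 328, 617, 1062, 536, 808 and 1359 genes (4 groups). Only the compared groups, hence fewer arrays, gave 957 (isorhamnetin) and 1476 (combination versus 13cRA).

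Lists past the test fell to 6, 4 and 11 with quantile normalization (isorhamnetin, 13cRA, combination versus 13cRA) and to 6 and 10 with the deposited values (isorhamnetin, combination versus 13cRA); the cause was not tested. With an estimated correlation 0, 1, 2, 0, 3 and 3 lists passed in the 6 contrasts, and with the replicate block as well 0, 0, 1, 0, 1 and 0. With fry 11, 7, 18, 12, 11 and 4 passed, where 15 of the 68 list calls ended and 10 were gained.

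Leaving out arrays or a replicate number gave 213 to 1702 genes (isorhamnetin), 623 to 1630 (13cRA), 1806 to 3741 (combination), 533 to 2228, 876 to 1987, 0 to 114 (interaction) and 2041 to 4561 (4 groups). Correlations were 0.79 to 0.82 and 0.62 to 0.69, shared calls 455 to 1131 and 157 to 1083, and genes past vehicle and both agents 144 to 518. Lists past the test were 9 to 14, 4 to 11, 12 to 17, 11 to 17, 4 to 12 and 5 to 9. Single arrays that moved a count over 1.5 times when left out were, for isorhamnetin, its replicates 1 (800) and 3 (999) and vehicle 1 (1132) and 3 (1026). For the combination versus 13cRA they were 13cRA 2 (1410) and combination 1 (1461) and 3 (1488), and for the interaction all vehicle arrays (73 to 79), isorhamnetin 1 (62), 13cRA 1 and 2 (66 and 64) and combination 1 (69). Calls shared by isorhamnetin and the combination were 590 and 712 without isorhamnetin 1 and 3 and 704 without vehicle 3, and genes past vehicle and both agents 344 without combination 1. Lists moved as far without vehicle 1 and isorhamnetin 3 (9 each, isorhamnetin), vehicle 1 and 2 and 13cRA 2 (4, 11 and 4, 13cRA) and combination 2 (11 and 4, combination versus 13cRA and versus isorhamnetin). The median of ribosomal proteins in the combination versus isorhamnetin was −0.07 to 0.09 over the leave-outs and turned positive without isorhamnetin replicate 3 and without replicate 3 (0.07); the cause was not tested.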

Other observations

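All tests of gene families in this part were chosen after the data had been seen; the gene lists had been set before.

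Neuronal and secretory genes moved without a common direction. Of 26 measured neuronal differentiation genes, 7 rose and 4 fell in the combination against vehicle (8 and 5 adjusted over the list alone), with a list test adjusted p of 0.242 and adjusted p = 0.567 with an estimated correlation; RET, at 4.72 ± 0.47, was among those that rose. Of 14 catecholamine and secretory granule genes, 2 rose and 3 fell (2 and 5 adjusted over the list alone; adjusted p = 0.465, adjusted p = 0.567 with an estimated correlation). Of 21 BCL2 family and apoptosis genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone; adjusted p = 0.21, adjusted p = 0.549 with an estimated correlation), where the list median was −0.01 and the mean 0.36. With isorhamnetin alone, BIK of this list, a BH3-only protein, was at least 2.13-fold higher.

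Of 18 interferon response genes, 1 rose and 0 fell in the combination (1 adjusted over the list alone; adjusted p = 0.405, adjusted p = 0.549 with an estimated correlation), while USP18, a protease induced by interferon that is not in that list, fell by 4.00 ± 0.21. Of 17 heat shock genes, 0 passed (0 adjusted over the list alone; adjusted p = 0.799, adjusted p = 0.903 with an estimated correlation). Of 36 translation initiation and elongation factors, 1 rose and 6 fell (0 and 6 adjusted over the list alone; adjusted p = 0.21, adjusted p = 0.573 with an estimated correlation). Of 11 Schwann cell and fibroblast markers, 4 rose and 2 fell (4 and 2 adjusted over the list alone; adjusted p = 0.53, adjusted p = 0.573 with an estimated correlation), with the list median at −0.08 and the mean at −0.29 although the test direction was up; COL1A2, one of these markers, fell by 4.80 ± 0.58.

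Among 14 gene families tested in 6 contrasts (84 tests), the zinc finger genes named ZNF had a lower interaction than other genes, with a median of −0.10 over 410 genes, 1 of them past the threshold upward and 1 downward (adjusted p = 1.33e-08, adjusted p = 0.041 with an estimated correlation). Against vehicle their median was 0.12 with isorhamnetin, where 36 rose and 3 fell (same test, adjusted p = 1.92e-05, 0.0994 with an estimated correlation). It was 0.06 with 13cRA and 0.06 in the combination. Gene families were not tested with the slide block.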
